A study of Mus musculus with 6 samples.

How the data were processed

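Tumors grown from CT26 cells, a colon carcinoma line of BALB/c mice, were dissociated into single cells and profiled by single-cell RNA sequencing. Per the labels' protocols, cells were captured in droplets with the DNBelab C4 kit and the libraries were read on a DNBSEQ-T7 instrument. The labels give 6 libraries in 2 groups of 3. The shNC tumors carried a control hairpin and the shCtsd tumors a hairpin against Ctsd, the gene of the lysosomal protease cathepsin D. All libraries are labelled batch 1, so no batch term was fitted. No label says that the 3 replicates of a group are separate animals. The p-values therefore measure only the spread between these libraries, which may be technical.

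The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and cell, made with PISA 1.0, per the file headers. They are whole numbers with no normalization, and cells had already been called. The submitters' processing notes name the mm10 build, Seurat and edgeR, without versions and without saying what each tool was used for. The aligner and the annotation are not given in the sources used here. Gene coordinates below are those of mm10 and were matched to the deposited gene symbols.

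The 6 matrices held 75244 barcodes. The strand setting of the counting is not given either, so overlapping genes cannot be told apart with certainty. Cells were kept with at least 300 genes, at least 500 UMIs and at most 20% mitochondrial counts, which left 74770. Scrublet in scanpy 1.11.5 was run per library. Its automatic threshold called between 0 and 4.56% of a library doublets. In shNC 1 it called none, so the 5% of cells with the highest scores were removed there. In all, 2655 cells (3.55%) were removed and 72115 kept. The labels state 68159 cells after quality control, and the filter behind that number was not used here.

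Counts were scaled to 10000 per cell and log-transformed. Clustering used 2000 variable genes, 30 principal components, 15 neighbors and Leiden resolution 1, with no integration of libraries. T and NK clusters and mononuclear phagocyte clusters were clustered again on their own. Clusters were named from markers of 27 cell types. The markers, the 26 gene lists, the designs, the rule for named genes and most alternatives were fixed before the data were examined. The thresholds of the naming were set after the clusters had been seen. They were a marker score of at least 3, at least 5 tumor markers, detection at 10 CPM, a CD8 to CD4 ratio of at least 10 and a macrophage margin of 1.75. Clusters 1, 16 and 18 and 6 subclusters stayed unnamed, because markers of another class led them, because they were shallow with no marker of their own leading, because their score was under the minimum or because they carried markers of both lineages. Names read as "like" the cell type, and the tumor cells are CT26-like by markers alone.

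The library, not the cell, was the replicate. Counts were summed per library and class where every library had at least 20 cells, which gave 12 classes, and over all kept cells. Levels are given as CPM, the counts scaled to a common total, computed from these sums. Sums were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, its expression filter and Benjamini-Hochberg adjustment over genes at 0.05. Log2 fold changes are shCtsd over shNC, with standard errors. Shares of cells were tested with an exact two-sided permutation test over the 20 assignments, whose smallest p is 0.1, adjusted over 18 classes. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over 324 tests of lists in 13 profiles (12 classes and all cells). Camera with an estimated correlation and fry were run beside it. The difference between the change in tumor cells and that in macrophages was tested in edgeR with library as a block. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9.

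The rule for named genes took Ctsd, then up to 10 rising and 10 falling genes past the adjusted threshold with a mean log2 CPM of at least 5 and no overlap between groups. Ribosomal, mitochondrial, hemoglobin and receptor segment genes and unnamed gene models were left out of that part. It added up to 4 members of each list described, those with the smallest p past the test first and then the most highly expressed, and Cd8a, Cd8b1, H2-K1, H2-D1, B2m, Gzmb, Prf1, Ifng, Pdcd1 and Cd274 in the classes they belong to. Which lists were described, and how many members of each, was chosen after the results were seen. Genes outside the rule were singled out after their values were seen, namely Krt8, Nlrp4e, Tpsab1 and other mast cell genes, Gm49369, the hemoglobin genes and, in macrophages, Il2rb.

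The lists covered class I antigen presentation, nonclassical class I, class II antigen presentation, interferon gamma response, type I interferon response, cathepsins and lysosomal proteases, lysosomal hydrolases and membrane proteins, autophagy, cytotoxic effectors, T cell exhaustion and checkpoints, naive and memory T cells, regulatory T cells, checkpoint ligands, chemokines, inflammatory macrophage genes, alternative macrophage genes, neutrophil granule and activation genes, cell cycle, hypoxia and glycolysis, oxidative phosphorylation, unfolded protein response, p53 and apoptosis, cholesterol synthesis, extracellular matrix and mesenchymal genes, dissociation and immediate early stress, and red blood cell transcripts.

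The tests were tried on simulated data drawn from the real means and library sizes. Changes were planted only in genes with a mean log2 CPM of at least 5, a level that 3629 of the tumor-cell genes reach. The shares recovered hold for such genes and not for lower ones. Each gene varied on its own, so variation shared by many genes of a library was not simulated. In tumor cells (17680 genes), 62.7% of genes changed 1.5-fold were recovered, 97.0% of those changed 2-fold and 100% of those changed 4-fold, with 22 false calls among 17480 unchanged genes. In macrophages (13060 genes) the shares were 20.9%, 95.5% and 100%, in CD8 T cells (10718 genes) 35.8%, 92.5% and 100%, in NK cells (9393 genes) 35.8%, 86.6% and 100%, and over all cells (19563 genes) 37.3%, 86.6% and 95.5%. Replicates of a group differed with a chi-square per degree of freedom of 97.2 to 194 over genes. Different cells taken from one tumor would also exceed counting noise, so this does not show that the libraries are independent samples, and they were treated as replicates because the labels number them so.

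The alternatives set beforehand were DESeq2 1.42.0 size factors in edgeR, the DESeq2 test, no filter on low counts, a filter of 10 CPM in 3 libraries, the replicate number as a block, each library left out, stricter and no cell filters, doublets kept, Leiden resolutions 0.5 and 2, an immune-cell denominator, edgeR on cell counts and a gate on Cd8a, Cd8b1 and Cd4 UMIs. Alternatives added after seeing the data were a tumor class with clusters 1 and 16, both libraries labelled 3 left out, and a T and NK total with unnamed subclusters.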

Results

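Single-cell transcriptomes were collected from CT26 tumors, a syngeneic model of colon carcinoma in BALB/c mice. The tumors carried a control hairpin (shNC, 3 libraries) or a hairpin against Ctsd (shCtsd, 3 libraries). The comparison asked how loss of cathepsin D in the tumor changes the tumor cells and the immune cells around them. The shNC libraries held 12133, 9983 and 12172 kept cells, with median depths of 7322, 12208 and 8889.5 UMIs per cell. The shCtsd libraries held 11002, 12634 and 14191 kept cells, with median depths of 8432.5, 6097.5 and 7446 UMIs. Total UMIs per deposited library were 201971204, 214156567 and 221963597 in shNC and 178734826, 184835405 and 214496880 in shCtsd. Values below are means ± SD over n = 3 libraries per group unless stated, log2 fold changes are shCtsd over shNC ± SE, and adjusted p-values are from edgeR for genes and from camera for gene lists.

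The targeted gene was examined first. Ctsd encodes cathepsin D, an aspartic protease of lysosomes, and lies on mm10 chromosome 7 (142375911 to 142388038, minus strand, protein-coding, ENSMUSG00000007891.16). In CT26-like tumor cells, Ctsd stood at 133, 130 and 102 CPM in shNC 1, 2 and 3, and at 89.0 and 62.3 CPM in shCtsd 1 and 2. The library labelled shCtsd 3 went against its label, with 143 CPM, above every shNC library. The group means were 122 ± 17.3 CPM in shNC and 98.2 ± 41.2 CPM in shCtsd (log2 fold change −0.38 ± 0.27, adjusted p = 0.990), a difference within the spread between libraries. Over all cells the values were 245 ± 25.1 and 210 ± 60.8 CPM (−0.32 ± 0.19, adjusted p = 0.615). In macrophages, which carry about 10 times the tumor-cell level, Ctsd was 1373 ± 90.7 CPM in shNC and 987 ± 120 CPM in shCtsd (−0.51 ± 0.11, adjusted p = 0.666), with each of the 3 shCtsd libraries below all shNC libraries. In plasmacytoid dendritic cells it was 245 ± 32.5 and 129 ± 13.6 CPM (−0.99 ± 0.23, adjusted p = 0.443), and in the other 9 classes fold changes lay between −0.42 and 0.28. The design took the hairpin to be in the CT26 cells only, so Ctsd in macrophages and other host cells does not measure the knockdown. With the libraries labelled shNC 3 and shCtsd 3 left out, the tumor-cell fold change was −0.88 (adjusted p = 0.209). Leaving out each library in turn, it ranged from −0.76 (without the library labelled shCtsd 3) to −0.14 (without shCtsd 2). Ctsd shares 6757 bases with the same-strand gene model Gm49369 (chromosome 7, 142371096 to 142382667), whose tumor-cell level was 4.56 CPM in shNC and 4.11 CPM in shCtsd, so counts in the shared part are uncertain. Because of the library labelled shCtsd 3, every direction below compares groups as labelled, not tumors with a measured loss of Ctsd.

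**Figure D1:**
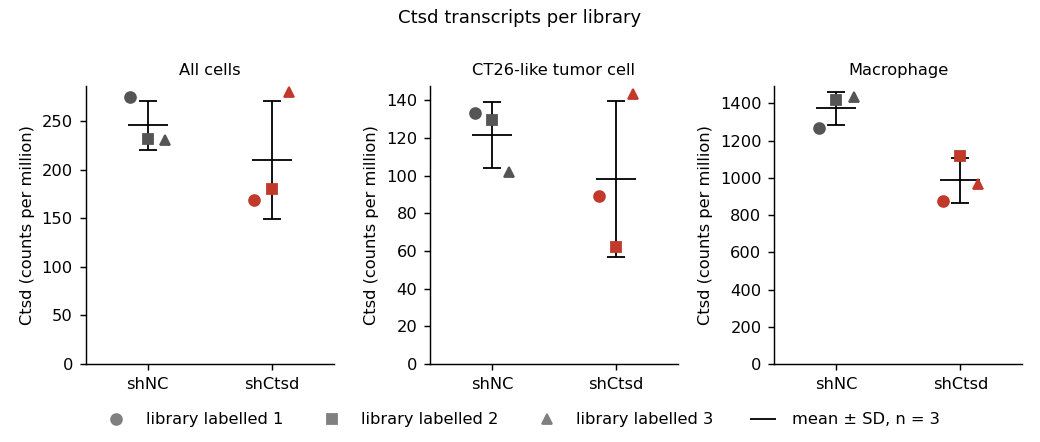
Ctsd level in CPM (vertical axis) in each library of shNC and shCtsd, for all cells, tumor cells and macrophages; points are libraries with marker shape for the labelled replicate number, and bars are mean ± SD (n = 3). In tumor cells the library labelled shCtsd 3 (143 CPM) sits above the 3 shNC libraries (102 to 133 CPM).

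Cells of the T and NK lineages took a larger mean share of the shCtsd tumors. CD8 T cells, the cytotoxic T cells, were 2.15, 2.54 and 1.61% of kept cells in shNC and 6.24, 4.46 and 5.52% in shCtsd, or 2.10 ± 0.47% against 5.41 ± 0.90%, a ratio of 2.57. NK cells were 1.49% against 3.96% (ratio 2.66), regulatory T cells 0.326% against 0.681% (2.09), other T cells 0.462% against 1.42% (3.06) and mast cells 0.209% against 0.408% (1.95). All T and NK classes together were 4.51 ± 0.49% against 11.6 ± 2.56% (2.58), and 5.08% against 13.1% with the unnamed T and NK subclusters counted in. For CD8 T cells, regulatory T cells, mast cells and the T and NK total, every shCtsd library lay above every shNC library, which gives an exact permutation p of 0.1, the smallest that 3 against 3 allows. No class passed after adjustment over 18 classes (CD8 T cells, adjusted exact p = 0.554). An edgeR test of the cell numbers gave an adjusted p = 0.115 for CD8 T cells. Without the libraries labelled shNC 3 and shCtsd 3 the CD8 ratio was 2.28 and the NK ratio 4.39. For NK cells the library labelled shCtsd 3 (1.93%) lay below the library labelled shNC 3 (2.19%).

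CT26-like tumor cells were 54.2 ± 10.2% of shNC and 43.4 ± 5.06% of shCtsd cells (ratio 0.801, exact permutation p = 0.2). With clusters 1 and 16, which carry tumor markers but stayed unnamed, they were 62.7% and 56.2%. Cluster 1, led by Mgp, Cp, Apod and Ogn, was 6.07% and 11.1%, and cluster 16, led by the hypoxia genes Ndufa4l2, Bnip3, Ero1l and Car9, was 2.39% and 1.67%. Macrophages were 12.04% and 13.4%, monocyte/macrophage intermediates 10.1% and 6.95%, and neutrophils 3.79% and 2.60%. Dendritic cell shares were 0.308% and 0.661% for the DC1 type, 0.552% and 0.814% for the DC2 type, 0.169% and 0.317% for the migratory type and 0.382% and 0.612% for the plasmacytoid type. The DC1 share was 1.21% in shCtsd 2, against 0.364% and 0.409% in the other shCtsd libraries, and the ratio was 2.15 with it and 1.26 without it. Fibroblasts were 2.19% and 1.79%, endothelial cells 0.517% and 0.435%, pericytes 0.229% and 0.207%, gamma delta T cells 0.132% and 0.182%, and B cells 0.128% and 0.196%. The remaining unnamed groups were cluster 18 (1.47% and 2.08%), 4 T and NK subclusters (0.267% and 0.711%, 0.177% and 0.442%, 0.0980% and 0.184%, 0.0274% and 0.0739%) and 2 phagocyte subclusters (0.0402% and 0.188%, 0.133% and 0.0722%). In the first of these phagocyte subclusters, of 85 cells in all, each shCtsd library lay above all shNC libraries (ratio 4.69, exact permutation p = 0.1). Among cells of the T cell classes, a gate on Cd8a or Cd8b1 UMIs without Cd4 UMIs gave 2.10% and 5.33%, and the CD4 gate 0.220% and 0.568%.

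**Figure D2:**
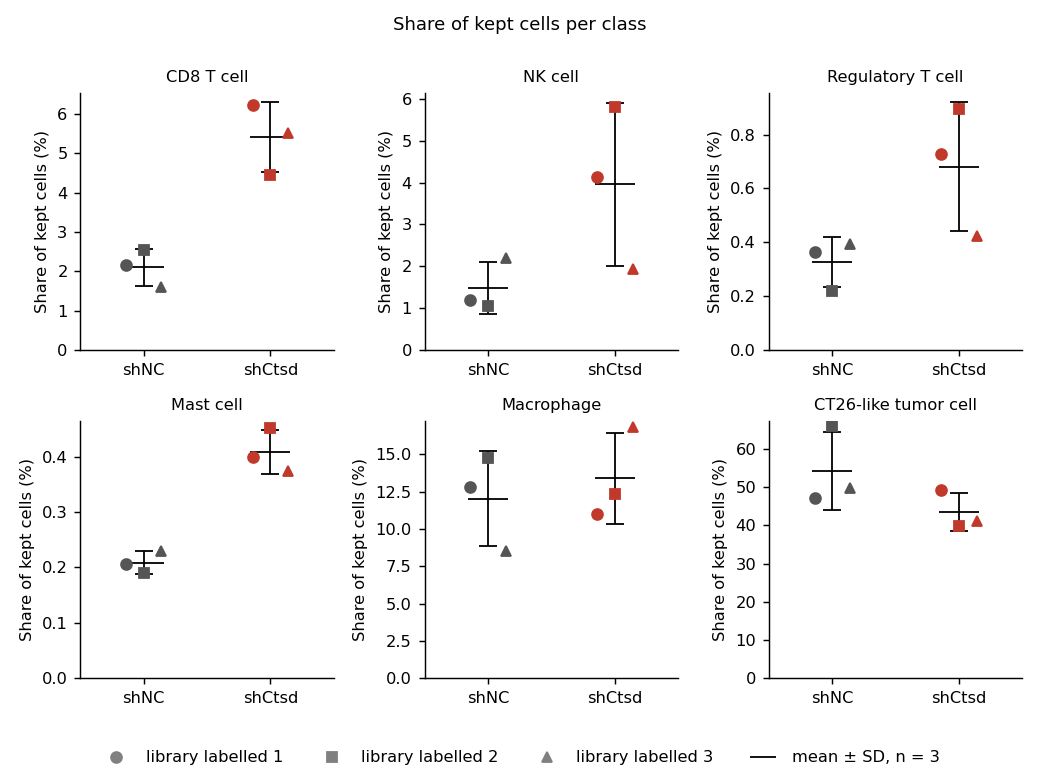
Share of kept cells in percent (vertical axis) per library for CD8 T cells, NK cells, regulatory T cells, mast cells, macrophages and tumor cells in shNC and shCtsd; points are libraries and bars are mean ± SD (n = 3). CD8 T cells span 1.61 to 2.54% in shNC and 4.46 to 6.24% in shCtsd.

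Over all cells of the tumor, the genes that rose in shCtsd included many genes of T and NK cells. They included Cd3g, a chain of the T cell receptor complex (18.0 ± 1.44 to 47.3 ± 8.36 CPM, log2 fold change 1.31 ± 0.15, adjusted p = 0.0313), and Il2rb, a subunit of the interleukin 2 receptor (20.6 ± 2.17 to 53.4 ± 6.49 CPM, 1.28 ± 0.11, adjusted p = 0.0307). Nkg7, a gene of cytotoxic granules, rose from 40.2 ± 7.50 to 105 ± 10.6 CPM (1.30 ± 0.14), Cblb from 19.99 ± 3.03 to 45.1 ± 1.26 CPM (1.09 ± 0.11) and Dock10 from 34.8 ± 5.70 to 70.2 ± 3.07 CPM (0.92 ± 0.11). For 41 of the 41 genes called, the class with the highest level, of the 12 classes compared, was a T or NK class. Mast cells were too few to be among the 12. In the list of T cell exhaustion and checkpoints, 3 of 16 members rose, among them Tox (8.13 to 23.6 CPM) and Cd160 (1.10 to 2.69 CPM), and 12 of 16 when adjusted over the list alone. The list was called higher at the preset correlation (median 0.69). With an estimated correlation its p = 0.0050 is before adjustment, and no list in any class passes adjustment there (smallest adjusted p = 0.570), so every list call here and below is lost at that correlation. Of 20 cytotoxic effectors, 2 rose, Fasl (2.21 to 6.35 CPM) and Nkg7, and 9 when adjusted over the list alone (median 0.83, p = 0.077 with an estimated correlation). In total edgeR called 41 genes higher and 0 lower of 19563 tested, with 2075 at an unadjusted p under 0.05, and DESeq2 called 524 higher and 48 lower. Groups did not overlap for 3583 genes (18.3%, where chance gives 10%). Most of these calls were made only with all 6 libraries in the fit. A fit of fewer libraries can detect fewer changes, so calls lost in it do not show dependence on a given library. Leaving out shCtsd 2 left 5 genes. Leaving out any one of shNC 1, shNC 2, the library labelled shNC 3, shCtsd 1 or the library labelled shCtsd 3 left 0. Leaving out both libraries labelled 3 also left 0, while the fold change of Cd3g was then 1.21 and that of Il2rb 1.45.

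In CT26-like tumor cells, several antigen presentation lists were called higher in the shCtsd group, and no single gene passed. The class I list holds the peptide-presenting molecules and their loading machinery, and 15 of its 17 members had a positive fold change (median 0.34). Within it, H2-K1 (chromosome 17, 33996017 to 34000347) was 879 ± 159 and 1215 ± 241 CPM (0.40 ± 0.17, adjusted p = 0.97965). H2-D1 (chromosome 17, 35262730 to 35267499) was 1906 ± 210 and 2471 ± 404 CPM (0.30 ± 0.14), and B2m, the light chain of class I molecules (chromosome 2, 122147686 to 122153083), was 1535 ± 274 and 1803 ± 405 CPM (0.16 ± 0.19). With 1 library left out B2m ranged from 0.04 (without the library labelled shCtsd 3) to 0.33 (without shCtsd 2), and without both libraries labelled 3 it was −0.048. Of the 8 nonclassical class I genes (median 0.40), H2-T22 was 77.0 and 109 CPM and H2-M3 31.9 and 42.5 CPM. The class II list, of molecules typical of professional antigen-presenting cells, had the largest median of these lists (1.26, 10 members), with Cd74 at 31.9 ± 19.6 and 81.7 ± 22.2 CPM and H2-Ab1 at 12.7 and 35.9 CPM. Of 23 interferon gamma response genes, 23 had a positive fold change (median 0.77), including Cxcl10 (55.6 and 99.0 CPM), Gbp2 (50.3 and 96.9 CPM) and Irf1 (51.0 and 94.1 CPM). The summed list was 878, 260 and 296 CPM in shNC and 781, 507 and 1295 CPM in shCtsd (exact permutation p = 0.3), so shNC 1 lay above 2 of the 3 shCtsd libraries, as it did for Cxcl10 and Gbp2. Without shNC 1 the fold changes of Cxcl10, Gbp2 and Irf1 were 1.62, 1.92 and 1.52, and that of Gbp2 was 0.22 without the library labelled shCtsd 3. Cd274, which encodes the checkpoint ligand PD-L1, was 6.42 and 11.4 CPM (0.76 ± 0.44), with 1.37 without shNC 1, 0.49 without shNC 2, 0.43 without the library labelled shCtsd 3 and 0.25 without both libraries labelled 3. Adjusted over the list alone, 0 class I genes, 1 nonclassical gene, 7 class II genes and 1 interferon gamma gene passed. With an estimated correlation the p-values were p = 0.186 for class I, p = 0.203 for nonclassical class I, p = 0.046 for class II and p = 0.167 for interferon gamma, none past adjustment. Without the libraries labelled shNC 3 and shCtsd 3 the class I median was 0.13 (adjusted p = 0.320), the nonclassical median 0.19 (0.398) and the interferon gamma median 0.07 (0.0958), so these calls ended, while class II kept its call (0.79). Leaving out shNC 1 moved the medians most, to 0.56 for class I, 0.74 for nonclassical class I and 1.67 for interferon gamma. Class I was 0.21 without shNC 2 and 0.22 without either library labelled 3, and interferon gamma was 0.49 without shNC 2 and 0.39 without the library labelled shCtsd 3. Without the library labelled shNC 3 alone the nonclassical call also ended (0.21, adjusted p = 0.0560). Markers of other cells moved with these lists. The summed T cell markers in tumor cells were 10.9 and 26.1 CPM, and the share of tumor-cell UMIs estimated to come from phagocytes was 0.914% and 1.04%. That phagocyte estimate held 50.5 of the 74.2 CPM of the class II list in shNC and 156 of 193 CPM in shCtsd.

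Other lists in tumor cells showed smaller medians. The type I interferon list was called higher (25 of 25 members positive, median 0.25, p = 0.369 with an estimated correlation), and leaving out the library labelled shCtsd 3 ended the call (adjusted p = 0.0689). Leaving out shNC 2 turned its median to −0.06, and leaving out shNC 1 or shCtsd 2 moved it to 0.78 or 0.39. Checkpoint ligands (median 0.11, 15 members, p = 0.185 with an estimated correlation) lost their call without any one of shNC 2, the library labelled shNC 3, shCtsd 1 or the library labelled shCtsd 3 (medians 0.16, 0.15, 0.08 and 0.06, and 0.19 without shCtsd 2). Cholesterol synthesis genes (18 members, median 0.17, p = 0.242 with an estimated correlation) lost theirs without shNC 2 or shCtsd 2 (medians 0.07 and 0.09, and 0.27 without the library labelled shNC 3). Immediate early and stress genes, which respond to tissue dissociation, were called higher (21 members, median 0.36, p = 0.048 with an estimated correlation). Egr1 was 773 and 994 CPM and Hsp90aa1 539 and 683 CPM. The median mitochondrial share of tumor cells was 0.266, 0.270 and 0.227% in shNC and 0.283, 0.288 and 0.310% in shCtsd. None of the calls in this paragraph passes adjustment with an estimated correlation. For each of these 4 lists, 0 genes passed when adjusted over the list alone. T cell lists were also called higher within tumor cells, beside the T cell markers given above: cytotoxic effectors (19 members, median 0.82, p = 0.110 with an estimated correlation, 8 genes adjusted over the list alone), exhaustion (15, 0.56, p = 0.019, 9 genes), naive and memory T cells (14, 0.40, p = 0.016, 3 genes) and regulatory T cells (12, 0.26, p = 0.084, 2 genes). The inflammatory macrophage list was called higher (17, 0.26, p = 0.231 with an estimated correlation, 2 genes adjusted over the list alone). Neutrophil granule genes (17, −0.13, p = 0.316 with an estimated correlation), oxidative phosphorylation genes (23, −0.05, p = 0.398) and red blood cell transcripts (5, −1.76, p = 0.162) were called lower, each with 0 genes adjusted over the list alone. Without both libraries labelled 3 the calls of cytotoxic effectors (0.59, adjusted p = 0.0693), inflammatory genes (0.05), oxidative phosphorylation (0.03) and red blood cell transcripts (−1.13) ended. The inflammatory, granule and oxidative phosphorylation calls were also lost with single libraries left out, with medians of 0.19 for inflammatory genes and −0.02 for oxidative phosphorylation without the library labelled shCtsd 3, and −0.05 for granule genes without shCtsd 1. Leaving out shCtsd 1 moved the naive and memory median to 0.21, leaving out the library labelled shNC 3 the regulatory T cell median to 0.53, and leaving out shCtsd 2 the red blood cell median to −5.17. At Leiden resolution 2 the red blood cell median turned to 0.46 and the call ended (adjusted p = 0.620). The proteases related to cathepsin D were not called. The cathepsin list had a median of −0.0064 and a mean of 0.036, which differ in sign (16 members, p = 0.740 with an estimated correlation, 1 gene higher adjusted over the list alone), with Ctsl at 1366 and 1264 CPM and Ctsz at 236 and 238 CPM. Lysosomal hydrolases (median 0.018), autophagy (0.027), cell cycle (−0.031), hypoxia (0.053) and p53 genes (0.080) were not called either. The cell cycle list was called lower without shNC 2 (−0.10, adjusted p = 0.000044), without shCtsd 2 (−0.08, adjusted p = 0.0017) and with clusters 1 and 16 in the class (−0.08), and its median turned positive without shNC 1 or either library labelled 3. The hypoxia list was called higher without shNC 1 or shCtsd 1 (0.14 each) and at 10 CPM or more in 3 libraries (0.08). The tumor class leaves out cluster 16, which carries tumor markers and is led by hypoxia genes, so the hypoxia values given here do not cover those cells. For single genes edgeR called 0 of 17680 (899 at an unadjusted p under 0.05, smallest adjusted p = 0.0713), and DESeq2 called 124 higher and 4 lower. Of those 124, 107 had their highest level in a T or NK class and 1 in tumor cells, of the 12 classes compared. Mast cells were not among the 12, and the 107 include the mast cell genes Tpsab1, Tpsb2, Cma1, Cpa3 and Mcpt4, so they are not all T or NK genes. Groups did not overlap for 11.1% of genes, where chance gives 10%. Without both libraries labelled 3, edgeR called 11 genes.

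**Figure D3:**
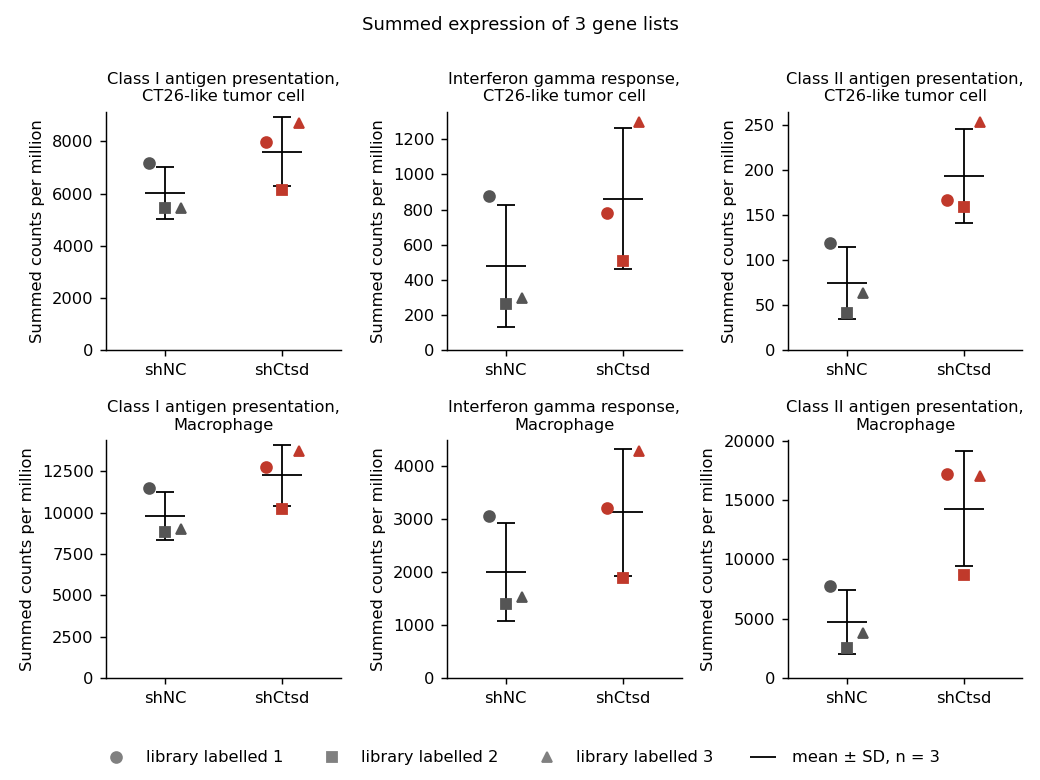
Summed CPM (vertical axis) of the class I, interferon gamma and class II lists per library in tumor cells and macrophages of shNC and shCtsd; points are libraries and bars are mean ± SD (n = 3). In tumor cells the class II sum averages 74.2 CPM in shNC and 193 CPM in shCtsd, and the class I sum 6031 and 7608 CPM.

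In macrophages of the shCtsd group the class II list was called higher and the list of alternative activation lower. Cd74, the class II invariant chain (chromosome 18, 60803848 to 60812652), was 1968 ± 956 CPM in shNC and 5744 ± 1688 CPM in shCtsd (1.52 ± 0.36, adjusted p = 0.698), and H2-Aa was 784 and 2589 CPM, H2-Ab1 934 and 2937 CPM and H2-Eb1 626 and 2202 CPM. All 9 class II members had a positive fold change (median 1.52), 8 of 9 passed when adjusted over the list alone, and the list was called (p = 0.075 with an estimated correlation). The subclusters that make up the class differed with it. Subcluster 0, led by C1qc, C1qa and Apoe with class II genes among its leading genes, held 28.4, 6.71 and 11.2% of macrophages in shNC and 29.98, 17.7 and 39.8% in shCtsd. Arg1, the arginase typical of alternatively activated macrophages (chromosome 10, 24915221 to 24927484), was 1154 ± 366 and 425 ± 96.1 CPM (−1.48 ± 0.26, adjusted p = 0.666), with 3 of 3 shCtsd libraries below all shNC libraries. None of the list calls in macrophages passes adjustment with an estimated correlation. Spp1 was 1580 and 1154 CPM and Mrc1 630 and 456 CPM. The alternative macrophage list was called lower (20 members, median −0.34, 1 gene adjusted over the list alone, p = 0.368 with an estimated correlation), and the call ended without any one of shNC 2, the library labelled shNC 3 or the library labelled shCtsd 3 (medians −0.14, −0.14 and −0.09, and −0.58 without shNC 1). Interferon gamma genes (22 members, median 0.67, 0 genes adjusted over the list alone, p = 0.182 with an estimated correlation) and class I genes (17, 0.32, 0 genes, p = 0.171) were called higher. Among them Cxcl9 was 445 and 771 CPM, Irf8 236 and 299 CPM, H2-K1 1269 and 1784 CPM, H2-D1 2624 and 3433 CPM and B2m 2710 and 3185 CPM. The groups overlapped for Cxcl9. It was 816, 849 and 1172 CPM in shNC 1, shCtsd 1 and the library labelled shCtsd 3. In shNC 2, the library labelled shNC 3 and shCtsd 2 it was 268, 251 and 293 CPM. Cxcl9 ranged from 0.34 without the library labelled shCtsd 3 to 1.53 without shNC 1, and B2m from 0.08 to 0.35 without the same libraries. Cd274 was 97.2 and 150.3 CPM. The class I median was 0.52 without shNC 1 and 0.18 without both libraries labelled 3, and stayed called. Hypoxia and glycolysis genes were called lower (24, median −0.17, 0 genes adjusted over the list alone, p = 0.052 with an estimated correlation), with Gapdh at 2613 and 2455 CPM and Pkm at 1171 and 1093 CPM. The inflammatory list (0.19) and the cathepsin list (−0.06, Ctsb 2351 and 2222 CPM, Ctss 1921 and 2393 CPM) were not called. The inflammatory list was called higher without shCtsd 2 (0.38, adjusted p = 0.0015) and with the replicate number as a block (0.18, adjusted p = 0.0477), while its median was 0.37 without shNC 1, 0.012 without the library labelled shCtsd 3 and −0.05 without both libraries labelled 3. A marker from the NK cell list moved here too, Il2rb, at 4.33, 4.88 and 4.61 CPM in shNC and 10.7, 8.87 and 10.4 CPM in shCtsd. edgeR called 0 of 13060 genes (811 at an unadjusted p under 0.05), and DESeq2 13 higher and 6 lower. Groups did not overlap for 11.2% of genes, where chance gives 10%. Without both libraries labelled 3 edgeR called 1 gene, the class II median was 1.12, the interferon gamma median 0.17 and the alternative median −0.04, the last no longer called. Leaving out shNC 1 moved the interferon gamma median to 1.08, and leaving out shNC 2 or the library labelled shCtsd 3 moved it to 0.44 or 0.34.

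In CD8 T cells, Cd8a and Cd8b1 helped to name the class, so their level within it says little. Cd8a was 551 ± 44.8 and 547 ± 95.3 CPM, Cd8b1 703 and 672 CPM, and the effector genes Gzmb, Prf1 and Ifng were 554 and 618, 1184 and 957, and 134 and 172 CPM. Pdcd1, which encodes the PD-1 checkpoint receptor, was 463 ± 70.0 and 560 ± 49.5 CPM (0.26 ± 0.13). The cytotoxic list was not called (median 0.076, mean −0.25, which differ in sign), with Nkg7 at 2327 and 2486 CPM and Ccl5 at 1064 ± 1153 and 1877 ± 1581 CPM. The exhaustion list was called higher (16 members, median 0.09, 1 gene adjusted over the list alone, p = 0.038 with an estimated correlation), with Tnfrsf9 at 996 and 1094 CPM and Nr4a2 at 704 ± 111 and 1029 ± 71.5 CPM (0.53 ± 0.12, adjusted p = 0.427). Naive and memory genes were called higher (12, median 0.15, 1 gene adjusted over the list alone, p = 0.064 with an estimated correlation), with Bcl2 at 207 and 244 CPM and Ccr7 at 185 and 142 CPM, and so were type I interferon genes (22, 0.37, 0 genes, p = 0.194), with Ifi27l2a at 835 and 1029 CPM and Zbp1 at 82.9 and 108 CPM. Cell cycle genes were called lower (32, median −0.33, 0 genes adjusted over the list alone, p = 0.095 with an estimated correlation), with Top2a at 219 and 169 CPM and Ube2c at 205 and 176 CPM. Immediate early and stress genes were called higher (21, median 0.66, 15 genes adjusted over the list alone, p = 0.034 with an estimated correlation), with Junb at 791 and 1082 CPM and Jund at 648 and 792 CPM. The median mitochondrial share of CD8 T cells was 0.635, 0.677 and 0.614% in shNC and 0.712, 0.722 and 0.742% in shCtsd, and dissociation was not told apart from signaling. With an estimated correlation the stress call, like the others here, does not pass adjustment (smallest adjusted p of any list = 0.570). Class II genes (7, median 1.54, 5 genes adjusted over the list alone, p = 0.042 with an estimated correlation) and interferon gamma genes (21, median 0.48, 3 genes adjusted over the list alone, p = 0.249 with an estimated correlation) were called higher, the latter only with both libraries labelled 3 in the fit (−0.02 without them). The mast cell transcript Tpsab1 was 4.60 and 22.6 CPM in these cells. The subclusters that hold most CD8 T cells differed between libraries. Subcluster 1 held 51.7, 24.4 and 18.9% in shNC and 17.5, 16.9 and 59.8% in shCtsd, and subcluster 2 held 14.6, 23.2 and 27.0% and 48.7, 59.0 and 12.2%. For single genes edgeR called 0 of 10718 (954 at an unadjusted p under 0.05), and DESeq2 19 higher and 4 lower. Groups did not overlap for 15.1% of genes, where chance gives 10%. The exhaustion call ended without shNC 2 (0.13) or the library labelled shCtsd 3 (0.12), and the naive and memory call without shNC 1 (0.17) or shCtsd 1 (0.11). With their calls kept, the exhaustion median was 0.25 without shNC 1 and 0.20 without shCtsd 2, and the naive and memory median was 0.25 without shNC 2, 0.32 without the library labelled shNC 3 and 0.22 without the library labelled shCtsd 3. The type I interferon median was 0.76 without shNC 1 and 0.17 without shNC 2, the cell cycle median was −0.17 without the library labelled shNC 3, and the sign of Nkg7, Ccl5, Ccr7, Ifi27l2a, Cd8a, Cd8b1 and Gzmb turned with the library left out. Without the library labelled shCtsd 3, edgeR called 17 genes, and without both libraries labelled 3 it called 5. The cytotoxic list then had a median of −0.52 and was called lower (adjusted p = 0.0216).

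In NK cells the cell cycle list was called lower in shCtsd, in a class whose make-up also differed. Subcluster 4 held 18.5, 17.0 and 18.4% of NK cells in shNC and 29.8, 40.8 and 23.4% in shCtsd, and subcluster 0 held 71.2, 62.3 and 65.9% and 57.9, 44.3 and 62.0%. Top2a, a topoisomerase of dividing cells, was 150 ± 36.9 and 94.1 ± 12.3 CPM (−0.70 ± 0.18, adjusted p = 0.240), and Ube2c was 149 and 118 CPM. The list had a negative fold change for all 31 members (median −0.41, 10 genes adjusted over the list alone, p = 0.065 with an estimated correlation). Stress genes were called higher (20, median 0.38, 10 genes adjusted over the list alone, p = 0.040 with an estimated correlation), with Junb at 1019 and 1278 CPM and Btg2 at 815 and 1003 CPM. The median mitochondrial share of NK cells was 0.544, 0.583 and 0.565% in shNC and 0.604, 0.745 and 0.656% in shCtsd. Neither call passes adjustment with an estimated correlation. The cytotoxic list was not called (median −0.20), with Gzma at 5733 and 5917 CPM, Gzmb at 1898 and 1531 CPM and Prf1 at 1190 and 993 CPM. It was called lower without shNC 2 (−0.25, adjusted p = 0.0327) or shCtsd 1 (−0.28, adjusted p = 0.0007), while its median was −0.0024 without shNC 1, −0.0005 without shCtsd 2 and −0.03 without the library labelled shCtsd 3. Ccl5 was 1979 ± 70.9 and 3226 ± 950 CPM (0.66 ± 0.16, adjusted p = 0.235) and Ifng 43.5 and 69.8 CPM. edgeR called 0 of 9393 genes (964 at an unadjusted p under 0.05, smallest adjusted p = 0.0939), and DESeq2 2 higher and 1 lower. Groups did not overlap for 15.5% of genes, where chance gives 10%. Without the library labelled shCtsd 3, edgeR called 44 genes, and without both libraries labelled 3 it called 36, when Ccl5 (0.92, adjusted p = 0.0080) and Top2a (−0.99, adjusted p = 0.0151) passed. The cell cycle median was then −0.65.

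In monocyte/macrophage intermediates the class II list was called higher, as in macrophages (8 members, median 1.35, 8 genes adjusted over the list alone, p = 0.042 with an estimated correlation). Cd74 was 1721 ± 427 and 4466 ± 1412 CPM and H2-Ab1 958 and 2596 CPM. The make-up of this class differed too. Subcluster 13, led by H2-Ab1, H2-Aa and H2-Eb1, held 7.83, 2.39 and 1.15% of the intermediates in shNC and 15.2, 4.31 and 17.1% in shCtsd, subcluster 11 held 8.90, 9.33 and 10.7% and 21.7, 15.6 and 10.6%, and subcluster 6 held 37.7% in shNC 1 and at most 10.9% elsewhere. Hypoxia and glycolysis genes were called lower (24 members, median −0.34, 0 genes adjusted over the list alone, p = 0.136 with an estimated correlation), with Gapdh at 3417 and 2807 CPM and Aldoa, whose symbol stands for 2 gene models on chromosome 7, at 1710 and 1431 CPM. In neutrophils the granule and activation genes were called lower (17, median −0.38, 1 gene adjusted over the list alone, p = 0.044 with an estimated correlation), with S100a9 at 27604 ± 1322 and 20514 ± 5092 CPM and S100a8 at 14875 and 10777 CPM. With an estimated correlation none of these 3 calls passes adjustment. Without shNC 1 the granule median was −0.05. The hypoxia median in the intermediates was −0.17 without the library labelled shNC 3 alone, still called (adjusted p = 0.0009), and −0.17 without both libraries labelled 3, no longer called (adjusted p = 0.0529). For single genes edgeR called 0 in the intermediates (541 at an unadjusted p under 0.05, DESeq2 10 higher and 3 lower), 0 in neutrophils (171, DESeq2 0 and 1), 0 in fibroblasts (414, DESeq2 8 and 1) and 0 in endothelial cells (334, DESeq2 2 and 1). It called 0 in DC2-type dendritic cells (210, DESeq2 0 and 0), 0 in plasmacytoid dendritic cells (244, DESeq2 0 and 2), 0 in regulatory T cells (183, DESeq2 0 and 0) and 0 in other T cells (248, DESeq2 0 and 0).

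The change in tumor cells was compared with that in macrophages of the same tumors, since the knockdown is labelled as one of CT26 tumors. For Ctsd the difference between these changes was 0.07 (adjusted p = 1 by edgeR), and its sign turned without the library labelled shNC 3 (−0.08) and without the library labelled shCtsd 3 (−0.26). Of 17690 genes tested, edgeR called 0 higher and 3 lower in tumor cells relative to macrophages, the hemoglobin genes Hba-a2, Hbb-bs and Hbb-bt, which were singled out after their values were seen. There were 709 genes at an unadjusted p under 0.05, and DESeq2 called 21. The 3 calls were lost without shNC 2, without the library labelled shNC 3 or without shCtsd 2.

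Across the 13 profiles, camera called 121 of 324 tests of lists, 79 higher and 42 lower in shCtsd. With an estimated correlation 0 tests passed adjustment (smallest adjusted p = 0.570), and with fry 0 (smallest adjusted p = 0.175). Class II antigen presentation was called higher in 12 of 13 profiles, stress genes in 11, interferon gamma response in 10, nonclassical class I in 8 and class I in 6. Their medians reached 1.94, 0.66, 0.79, 0.59 and 0.53. The 13 profiles include the sum over all cells. Free RNA from phagocytes was estimated for tumor cells only, so its part in the class II calls of other classes is not known. Among T cell lists, exhaustion was called higher in 6 profiles, cytotoxic effectors in 5, naive and memory genes in 5, and the regulatory T cell list higher in 4 and lower in 2 of 10. The smallest p-values with an estimated correlation were p = 0.041 for class II, p = 0.012 for stress, p = 0.167 for interferon gamma, p = 0.108 for nonclassical class I, p = 0.170 for class I and p = 0.0050 for exhaustion. Without the libraries labelled shNC 3 and shCtsd 3 camera called 90 tests.

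**Figure D4:**
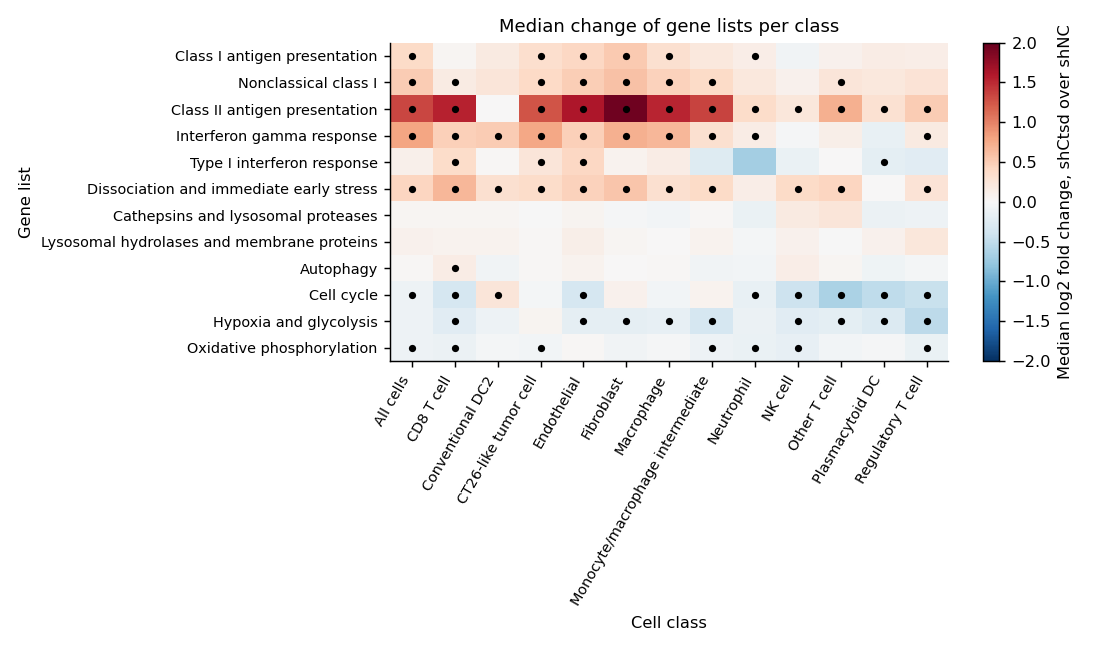
Median log2 fold change (shCtsd over shNC, color limited to −2 to 2) of 12 gene lists (vertical axis) in 13 profiles (horizontal axis), 3 libraries per group; a dot marks an adjusted camera p under 0.05 at the preset correlation. Class II carries a dot in 12 of 13 profiles, with medians up to 1.94.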

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

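The test of an exchange between the libraries labelled shNC 3 and shCtsd 3 was chosen after the results were seen, and the criterion of the test on fewer tumor cells was rewritten after its result was seen.

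The change between groups differed between tumor cells and macrophages for 3 hemoglobin genes, which encode the oxygen carrier of red blood cells. The fold change in tumor cells minus that in macrophages was −5.43 for Hba-a2 (adjusted p = 0.0043 by edgeR), −5.50 for Hbb-bs (adjusted p = 0.0078) and −4.48 for Hbb-bt (adjusted p = 0.0078). In macrophages Hba-a2 was 36.5 CPM in shCtsd 2 and between 0.284 and 1.20 CPM in the other 5 libraries. In tumor cells it was 1.16, 17.1 and 20.5 CPM in shNC and 0.191, 11.3 and 0.502 CPM in shCtsd. Without shNC 2, without the library labelled shNC 3 or without shCtsd 2, edgeR called 0 genes in this comparison. No explanation was tested for this pattern.

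In tumor cells, Ctsd of the library labelled shCtsd 3 lies above the shNC libraries. Free RNA from phagocytes is argued against, since with the phagocyte estimate removed the library still lay 21.0 CPM above the shNC mean, more than the shNC SD of 18.8 CPM. From Ctsd alone a swapped label cannot be told apart from variation, because the gap between the lowest shNC library and the higher of the other 2 shCtsd libraries was 6.73 CPM, within that SD. The SD includes the library labelled shNC 3, itself in doubt. Its value less the estimate (88.8 CPM, against 123 and 119 CPM in shNC 1 and 2) widens the SD, so this comparison could not decide. Over all tumor-cell genes, the split that exchanges the libraries labelled shNC 3 and shCtsd 3 called 69 genes. Each of the other 9 splits, the labelled one included, called 0. An exchange may be the source, as a hypothesis, with its form left open. The count alone cannot show an exchange, because a different split led in macrophages (132 genes) and fibroblasts (50 genes). The exchanging split also called 7 genes in CD8 T cells and 6 in other T cells, the most of any split. It called 0 in macrophages, fibroblasts and DC2-type cells and 1 in endothelial cells, where other splits called up to 132, 50, 4 and 8. NK shares (2.19% and 1.93%) go against the labels. Macrophage Ctsd (1434 and 968 CPM), CD8 T cell shares (1.61% and 5.52%) and the genes called over all cells (41 as labelled, 1 exchanged) follow them. For macrophage Ctsd and CD8 T cell shares the labelled groups do not overlap, so the libraries labelled 3 had to lie on their labelled sides. Macrophages are host cells, so their Ctsd does not measure the knockdown. A difference between stocks of CT26 cells was not tested, and no library was regrouped.

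CD8 T cells take a larger share of cells in every shCtsd library than in any shNC library. The CD8 share of immune cells was also higher in every shCtsd library than in any shNC library. The group means differed by 7.97 percentage points, with a larger SD of 4.64 (exact permutation p = 0.1, adjusted exact p = 0.467 over immune classes). The criterion of this test was rewritten after its result was seen, so it does not count as set in advance. Fewer tumor cells alone would raise the shares of all other classes by the same ratio. Immune cells as a whole were 32.2 ± 6.47% of shNC and 37.6 ± 5.45% of shCtsd cells, a ratio of 1.17. The CD8 ratio was 2.57. These values argue against fewer tumor cells alone as the source of the CD8 difference. Loss of shallow T cells from the shNC libraries is argued against, because among cells with at least 5000 UMIs the lowest shCtsd library lay 2.36 percentage points above the highest shNC library, with a larger SD of 0.540. An effect of the hairpin stays open as a hypothesis, beside differences between mice, tumor sizes or dissociations that the labels do not record.

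Class I, interferon gamma and class II lists were called higher in tumor cells of the shCtsd group. The phagocyte estimate covers 88.6% of the difference in summed class II CPM, so free RNA from phagocytes may account for most of the class II difference. It covers 2.48% of the difference for class I and 3.62% for interferon gamma, which argues against this source for those 2 lists. A response of tumor cells to the hairpin and one to the T and NK cells around them both stay open and were not tested apart. The class I and interferon gamma sums were highest in shNC 1, shCtsd 1 and the library labelled shCtsd 3, which is not the labelled grouping. There they were 7179, 7996 and 8688 CPM for class I and 878, 781 and 1295 CPM for interferon gamma. In shNC 2, the library labelled shNC 3 and shCtsd 2 they were 5459, 5455 and 6140 CPM, and 260, 296 and 507 CPM. The source of that other grouping was not tested. The medians without both libraries labelled 3 were 0.13 and 0.07 for class I and interferon gamma, so the calls of these 2 lists also rest on the libraries in doubt.

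The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Over all cells the labelled split called 41 genes and the highest other 13, so 1 of 10 splits gave as many. In the 12 classes the labelled split called 0 genes, so 10 of 10 splits gave as many. The highest other split called 7 in CD8 T cells, 4 in DC2-type cells, 69 in tumor cells, 8 in endothelial cells, 50 in fibroblasts, 132 in macrophages, 52 in monocyte/macrophage intermediates, 10 in neutrophils, 2 in NK cells, 6 in other T cells, 1 in plasmacytoid dendritic cells and 2 in regulatory T cells. For gene lists the labelled split called 121 and the highest other 140 (3 of 10 splits gave as many), and for the tumor and macrophage comparison 3 and 10 (3 of 10). The split of shNC 1, shCtsd 1 and the library labelled shCtsd 3 against the rest gave the 132, 52 and 50 genes, the 140 lists and the 10 genes. That split called 0 genes over all cells, in tumor cells, in CD8 T cells and in DC2-type cells. A structure of the samples other than the labelled groups may lie behind its calls, and none was tested.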

How the results depend on the processing

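The tumor class with clusters 1 and 16, the omission of both libraries labelled 3 and the T and NK total with unnamed subclusters were chosen after the data were seen. In every fit that leaves out libraries, a group of 2 is assumed to vary like the other.

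Apart from leaving out single libraries, fold changes of single named genes kept direction and side of the threshold in 889 settings, and 13 were reversed, 15 passed and 19 no longer passed. Fold changes of Ctsd over all cells, in tumor cells and in macrophages kept both in a further 34 settings, and in 18 with single libraries left out, while Ctsd in the interaction is counted with the single genes and reversed (values below). List medians did so in 370, with 7 reversed, 2 newly called and 63 no longer called, and ratios of shares kept direction in 163, with 2 reversed. With single libraries left out the numbers were 435 kept, 21 reversed, 1 newly past and 47 no longer past for genes, 173, 11, 5 and 15 for lists, and 110 kept and 4 reversed for ratios. A gene past the threshold in neither fit counts as kept where its direction held, and most of the kept gene settings are of this kind. The 47 no longer past are all genes called over all cells, where at most 5 of the 41 calls outlasted the omission of a library. The ratio for CD8 T cells stayed above 1 in each setting run, from 2.16 to 2.87. The number of lists called ranged from 0 to 152 over settings and from 103 to 147 with single libraries left out.

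The DESeq2 test called 572 genes over all cells, 23 in CD8 T cells, 128 in tumor cells, 3 in endothelial cells, 9 in fibroblasts, 19 in macrophages, 13 in monocyte/macrophage intermediates, 1 in neutrophils, 3 in NK cells, 2 in plasmacytoid dendritic cells and 21 in the tumor by macrophage interaction. With no filter on low counts edgeR called 249 in CD8 T cells, 33 in DC2-type cells, 2 in tumor cells, 69 in endothelial cells, 176 in fibroblasts, 1 in macrophages, 69 in monocyte/macrophage intermediates, 27 in neutrophils, 115 in NK cells, 16 in other T cells, 68 in plasmacytoid dendritic cells, 8 in regulatory T cells and 66 in the interaction. At least 10 CPM in 3 libraries gave 3 in regulatory T cells and 0 in the interaction, where fewer genes were tested. The cause of the other differences was not tested.

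With the replicate number as a block, edgeR called 0 genes over all cells, 1 in NK cells and 1 in regulatory T cells. Gzma in NK cells was then −0.0062 and the cathepsin list in tumor cells 0.027. Deviations of libraries with the same number correlated at −0.51, −0.23 and −0.60 over all cells. In macrophages they correlated at −0.16, 0.27 and −0.58. No label says that the numbers pair the libraries, and these correlations cannot settle it, because deviations from a mean of 3 libraries are tied to each other. With doublets kept, 25 genes were called over all cells, all of them among the 41. The stricter cell filter gave 0 in the interaction. Leiden resolution 0.5 gave 1 gene in macrophages, 0 in the interaction, −0.22 for Ctsd in DC2-type cells and −0.0084 for Gzma in NK cells. Leiden resolution 2 gave 0 in the interaction, −0.0089 for Gzma in NK cells, 0.040 for the cathepsin list and 0.46 for red blood cell transcripts in tumor cells. With clusters 1 and 16 in the tumor class the cathepsin median was 0.017. Over immune cells the macrophage ratio was 0.909. Camera with an estimated correlation called 0 lists and fry 0. The cause was not tested for these.

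With the libraries labelled shNC 3 and shCtsd 3 left out, edgeR called 0 genes over all cells, 5 in CD8 T cells, 11 in tumor cells, 1 in macrophages, 36 in NK cells, 4 in other T cells and 8 in regulatory T cells. Fold changes reversed for Nkg7 (−0.19), Ccl5 (−0.52), Ccr7 (0.25) and Gzmb (−0.56) in CD8 T cells, B2m (−0.048) and Gbp2 (−0.11) in tumor cells, Ctss (−0.087) and B2m (−0.013) in macrophages, and Ctsd in the interaction (−0.40). List medians reversed for cell cycle in tumor cells (0.10), inflammatory genes in macrophages (−0.051) and cytotoxic effectors in CD8 T cells (−0.52). The macrophage ratio was 0.846. Fewer libraries were fitted here, and the cause was not tested further.

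With single libraries left out, numbers of genes called ranged from 0 to 5 over all cells, 0 to 17 in CD8 T cells (17 without the library labelled shCtsd 3), 0 to 1 in endothelial cells, 0 to 2 in monocyte/macrophage intermediates, 0 to 44 in NK cells (44 without the library labelled shCtsd 3), 0 to 2 in other T cells, 0 to 4 in plasmacytoid dendritic cells, 0 to 6 in regulatory T cells and 0 to 5 in the interaction. In CD8 T cells Nkg7 ranged from −0.11 to 0.25 (negative without shNC 2 or either library labelled 3), Ccl5 from −0.14 to 2.21 (negative without the library labelled shCtsd 3), Ccr7 from −0.82 to 0.019 (positive without the library labelled shNC 3) and Ifi27l2a from −0.064 to 0.94 (negative without shNC 2). Cd8a ranged from −0.18 to 0.063 (positive without shNC 1, shCtsd 1 or shCtsd 2), Cd8b1 from −0.24 to 0.023 (positive without shCtsd 1) and Gzmb from −0.39 to 0.43 (negative without either library labelled 3). Ctsd ranged from −0.16 to 0.64 in DC2-type cells (negative without shNC 1 or shCtsd 1), from −0.36 to 0.13 in fibroblasts (positive without shNC 1, shCtsd 1 or shCtsd 2) and from −0.26 to 0.43 in the interaction (negative without either library labelled 3). Gzma in NK cells ranged from −0.13 to 0.10 (negative without shNC 2 or shCtsd 1).

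Among list medians with single libraries left out, type I interferon in tumor cells ranged from −0.058 to 0.78 (negative without shNC 2), cathepsins in tumor cells from −0.073 to 0.047 (positive without shNC 1, shNC 2 or shCtsd 2) and cell cycle in tumor cells from −0.10 to 0.036 (positive without shNC 1 or either library labelled 3). Cathepsins in macrophages ranged from −0.087 to 0.0056 (positive without shCtsd 2) and cytotoxic effectors in CD8 T cells from −0.19 to 0.27 (negative without shNC 2 or either library labelled 3). The macrophage ratio ranged from 0.970 to 1.26 (under 1 without either library labelled 3) and the pericyte ratio from 0.647 to 1.19 (above 1 without shNC 1 or shCtsd 1). Fewer libraries were fitted in these settings.

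Depth limits the rarer classes. Regulatory T cells had 4840 genes tested and plasmacytoid dendritic cells 4833, against 17680 in tumor cells. Mast cells, B cells, DC1-type and migratory dendritic cells, gamma delta T cells and pericytes had too few cells in at least 1 library for a test of genes.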

Other observations

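Which lists and genes are described here was chosen after the results were seen.

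At the preset correlation, stress, metabolic and growth lists were called in many classes. With an estimated correlation no list passes adjustment in any class (smallest adjusted p = 0.570), and the p-values below are before adjustment. Immediate early and stress genes, which respond to dissociation as well as to signaling, were called higher in 11 of 13 profiles (medians 0.0024 to 0.66). Over all cells their summed level was 5405 CPM in shNC and 7670 CPM in shCtsd, with 0 of 21 genes adjusted over the list alone and p = 0.104 with an estimated correlation. Hypoxia and glycolysis genes were called lower in 9 of 13 (−0.52 to 0.05, smallest p = 0.022 with an estimated correlation). Cell cycle genes were called lower in 8 and higher in 1 (−0.63 to 0.24, smallest p = 0.065 with an estimated correlation), and oxidative phosphorylation genes lower in 7 (−0.17 to 0.02, smallest p = 0.135). In regulatory T cells the hypoxia median was −0.52 (17 members, 2 lower adjusted over the list alone, p = 0.022 with an estimated correlation). In other T cells the cell cycle median was −0.63 (14 members, 3 lower adjusted over the list alone, p = 0.079 with an estimated correlation).

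The remaining lists were called in few profiles. Chemokines were called higher in 1 and lower in 2 of 13 (−0.90 to 0.18, smallest p = 0.020 with an estimated correlation). Unfolded protein response genes were called higher in 1 and lower in 2 (−0.29 to 0.12, p = 0.027 with an estimated correlation) and extracellular matrix genes lower in 2 (−0.20 to 0.10, p = 0.160). Autophagy was called higher in 1 (−0.08 to 0.15, p = 0.120 with an estimated correlation), cholesterol synthesis higher in 2 (−0.28 to 0.31, p = 0.242), checkpoint ligands higher in 1 (−0.15 to 0.16, p = 0.185), and type I interferon higher in 3 and lower in 1 (−0.68 to 0.42, p = 0.141). Inflammatory macrophage genes were called higher in 2 (−1.38 to 0.33, p = 0.186 with an estimated correlation), alternative macrophage genes lower in 3 of 12 (−1.04 to 0.13, p = 0.062), neutrophil granule genes lower in 4 (−1.70 to 0.53, p = 0.014) and red blood cell transcripts lower in 2 of 3 (−1.76 to 3.97, p = 0.162). Cathepsins (−0.14 to 0.24, p = 0.228 with an estimated correlation), lysosomal hydrolases (−0.05 to 0.22, p = 0.113) and p53 genes (−0.16 to 0.13, p = 0.162) were called in 0 of 13.

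Class II and stress lists were also called higher in fibroblasts and endothelial cells at the preset correlation, and no difference between classes was tested. The stress median was 0.55 in fibroblasts and 0.46 in endothelial cells. The median mitochondrial share was 0.195, 0.252 and 0.230% in shNC and 0.277, 0.264 and 0.360% in shCtsd in fibroblasts, 0.493, 0.320 and 0.553% and 0.603, 0.769 and 0.537% in endothelial cells, and 0.395, 0.394 and 0.396% and 0.416, 0.455 and 0.450% in monocyte/macrophage intermediates. The class II median was 1.94 in fibroblasts (6 members, 5 adjusted over the list alone, p = 0.041 with an estimated correlation) and 1.61 in endothelial cells (p = 0.071). No phagocyte estimate was made for fibroblasts or endothelial cells, so free RNA from phagocytes was not tested as a source there. The cytotoxic list was called higher in fibroblasts too (11 members, median 1.35, 6 adjusted over the list alone, p = 0.0054 with an estimated correlation). None of these calls passes adjustment with an estimated correlation. The summed T cell markers in fibroblasts were 40.1 CPM in shNC and 64.4 CPM in shCtsd, and the summed NK markers 13.8 and 45.7 CPM.

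In tumor cells, Krt8, a keratin of epithelial cells, was 9.38, 11.8 and 162 CPM in shNC 1, shNC 2 and the library labelled shNC 3, and 132, 94.4 and 11.6 CPM in shCtsd 1, shCtsd 2 and the library labelled shCtsd 3. Nlrp4e was 0.526, 0.711 and 11.7 CPM, and 8.62, 5.60 and 0.598 CPM. Other values of the libraries labelled shNC 3 and shCtsd 3 follow the labels, among them macrophage Arg1 (1066 and 314 CPM), Ctsd in plasmacytoid dendritic cells (248 and 121 CPM), Il2rb over all cells (22.8 and 45.9 CPM), mast cell shares (0.230% and 0.373%) and the T and NK total (5.08% and 8.68%). In each of these the labelled groups do not overlap, so the libraries labelled 3 had to lie on their labelled sides. These values therefore cannot decide on an exchange. The share of other T cells does not follow the labels (0.690% and 0.662%). The split that exchanges these 2 libraries called 2 genes in NK cells and 2 in regulatory T cells, where the labelled split called 0. Another split also called 2 in regulatory T cells, and another called 1 in NK cells, so these small counts do not set the exchanging split apart. The mast cell tryptase Tpsab1 was 47.7 and 130.2 CPM over all cells and 4.32 and 12.1 CPM in tumor cells. Immune cells were 32.2% of kept cells in shNC and 37.6% in shCtsd.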
